A study of Homo sapiens with 6 samples.

How the data were processed

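Gene expression was measured on 6 Affymetrix whole-transcript human arrays, 3 of cells carrying an empty pLKO vector and 3 of cells carrying a short hairpin RNA against SND1. All 6 samples had received fluorouracil at 6 µg/mL for 48 h, per the labels. The labels name the cells as HepG2, an established hepatoblastoma-derived liver cancer line. The deposited values are log2 signals summarised with RMA (robust multi-array average), per the submitters' processing notes, a method that comprises background correction, quantile normalization between arrays and summarisation of probes. Its version, software and settings are not given in the sources used here. The deposited log2 values ranged from 0.342 to 13.5 over the transcript clusters, with array medians of 3.58 to 3.74. Signals that low are compressed towards the array's floor, so changes of dim genes are understated. The values carry no detection calls, and no scanner files were used here. The number of arrays, 3 per group, limits the precision.

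The table holds 70523 features. Control and other features outside the transcript clusters (2995) were left out, which left 67528 transcript clusters, the array's unit for 1 transcribed locus. GEO's platform annotation gave 1 gene symbol for 23781 clusters, several for 1543 and none in the table used for 42204. Symbols were set against a RefSeq gene table (GRCh38.p14) by Entrez identifier, and 0 differed. Of 21474 clusters with 1 symbol on numbered chromosomes, 99.8% carried in their identifier the chromosome that the RefSeq table gives for the symbol. Only clusters with 1 symbol were used for named genes, except that the cluster annotated with both SND1 and its intronic transcript SND1-IT1 is reported as the targeted gene. For the 479 genes with over 1 cluster, the cluster with the highest mean over all arrays stood for the gene, which gave 22465 named genes. No genome was given, and the RefSeq table's build is not known to be that of the array design, so no coordinates are printed.

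Groups and replicate numbers came from the sample titles. Each comparison was knockdown minus vector, fitted to the deposited log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term and all 6 arrays. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. Standard errors (SE) are limma's moderated ones, and the ± of a group mean is the SD of 3 arrays. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. For a single value, 3 arrays against 3 cannot give an exact two-sided permutation p under 0.1. No 2 arrays held the same values: the SD of the difference between arrays of one group was 0.147 to 0.193 over the named genes (log2).

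Before the data were examined, 25 gene lists were fixed for the tissue, the drug and the targeted protein, including markers of other cell types, together with the tests, the alternatives and the rule for named genes. Of 946 list entries, 830 were measured, 65 lay only on a cluster shared with another symbol and 51 had no row. Lists were tested with limma's camera with its preset correlation of 0.01, with adjustment over the 25 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move on balance one way and, in its mixed form, whether they change in either direction, and neither form compares the list with other genes. The rule named the SND1 cluster, UCA1 and MYB always. It also named up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold, with the groups not overlapping and a group mean above the median level of all genes. Only 5 rises met it. For each list it named up to 4 members past the threshold or, with none, the 2 members with the highest mean.

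Alternatives were the replicate number as a block, leaving out the dimmest 40% of features, renewed quantile normalization, median centring, a floor at the 30th percentile of all values, a variance trend with robust fitting, array weights, other ways of choosing a gene's cluster, a 2-fold minimum and leaving out each array in turn. Restricting the test to protein-coding genes was added after seeing the data. The scripts were tested on simulated data. Each gene had its real mean, a variance drawn from the distribution that limma fitted, and independent noise without differences between whole arrays. Of 22465 genes, 200 above the median level were changed. The knockdown comparison recovered 86% of those changed 1.5-fold and 96% of those changed 2-fold, with 7 false calls. These rates hold for such genes under limma's own assumptions. Of 25 simulated lists of independent genes, the 1 list shifted by -0.3 and 1 other were called. No called list of the real data had so large a mean shift as reported. Figures were drawn with matplotlib 3.10.9.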

Results

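The study asked which transcripts depend on SND1, a multifunctional RNA-binding nuclease and transcriptional coactivator, in cells under fluorouracil, a pyrimidine analogue that inhibits thymidylate synthase. The data comprised 3 arrays of vector cells and 3 of SND1 knockdown cells, labelled HepG2 and all exposed to fluorouracil at 6 µg/mL for 48 h. Untreated cells were not analysed here, so the comparison sets knockdown against vector cells under the drug and does not give the effect of the drug. All knockdown titles name the same hairpin, and the control vector was empty. Loss of SND1, effects of this hairpin on other transcripts and effects of carrying any hairpin therefore cannot be told apart. Array medians over the 67528 transcript clusters lay between 3.58 and 3.74 on the log2 scale. The first principal component over the brighter genes held 55.4% of the variance. Vector replicate 1 lay at -14.1, vector replicate 3 at 1.2 and knockdown replicate 1 at 10.3 on it, so arrays of 1 group were spread along the axis that also parted the groups. Over the named genes, vector replicate 3 and knockdown replicate 1 differed with an SD of 0.14, less than any pair of arrays of the same group (0.147 to 0.193).

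The targeted transcript was reduced. The chromosome 7 cluster annotated with SND1 and SND1-IT1 had a log2 signal of 7.28 ± 0.14 (SD, n = 3) in vector cells and 5.80 ± 0.10 (SD, n = 3) in knockdown cells. The change was -1.49 (SE 0.09, limma adjusted p = 0.0166 over all clusters), which left 35.6% of the vector signal (95% confidence interval 30.6 to 41.5). All knockdown arrays lay below all vector arrays, and the exact two-sided permutation p was 0.1, the smallest the design allows. Leaving out any array other than vector replicate 3 kept a change between -1.41 and -1.53 and raised limma's adjusted p to between 0.0773 and 0.249, above the threshold.

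Probes for many hepatocyte transcripts gave low signals on all 6 arrays labelled HepG2. ALB (albumin) and AFP (alpha-fetoprotein), both abundant secreted products of hepatoblastoma cells, had mean log2 signals of 1.83 and 1.5. The fibrinogen chain genes FGA, FGB and FGG had 1.92, 1.69 and 1.36, and APOB, the apolipoprotein of very-low-density lipoprotein, had 2.53. Each of these genes lay at or below the 18.1th percentile of named genes on every array. Of 45 measured hepatocyte plasma protein genes, 18 lay below the 25th percentile of named genes and 5 above the 75th, with APOA2 (7.79 ± 0.06 in vector cells, SD, n = 3) giving the highest signal. The 45 measured hepatocyte metabolic and regulatory genes had a median log2 signal of 3.60, and the 25 leukocyte and endothelial markers had 3.74. The 26 epithelial and cholangiocyte markers had 6.42, with KRT8 and KRT18 at 11.51 and 11.50. Of these genes, all except APOA2 were chosen after their levels were seen. Probes differ in how strongly they report a transcript, so these signals and percentiles describe the arrays and do not rank transcripts or lists by abundance.

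**Figure D1:**
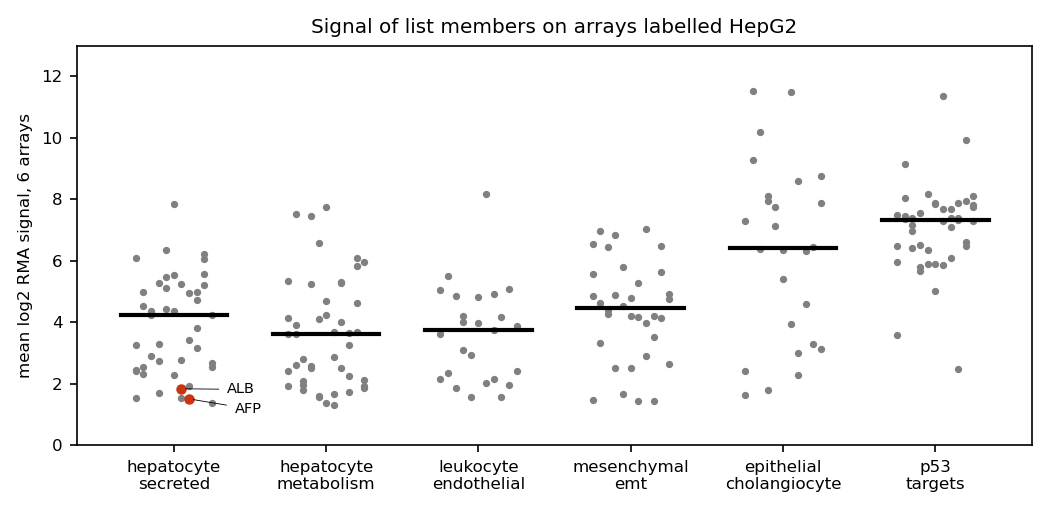
Mean log2 RMA signal over the 6 arrays (vertical axis) of each measured member (grey points) of 6 gene lists, with the median of each list as a black bar. ALB (1.83) and AFP (1.5) are marked in red near the bottom of the hepatocyte plasma protein list, whose median was 4.22, and the median of the epithelial list was 6.42. Signals of different probes do not rank transcripts by abundance.

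The knockdown cells had more genes lowered than raised. Of 22465 named genes, 31 fell and 7 rose at a limma adjusted p under 0.05, and all 38 had non-overlapping groups, which 17.9% of all named genes showed and chance gives for 10%. The largest fall was in MMP1, the interstitial collagenase, from 8.36 ± 0.13 to 7.07 ± 0.03 (SD, n = 3 each), a 2.45-fold decrease (log2 change -1.29, SE 0.07, adjusted p = 0.00273). CDH1, encoding E-cadherin of adherens junctions, fell 1.94-fold (-0.95, SE 0.07, adjusted p = 0.00954). LGALS4, a galectin of digestive epithelium, fell 1.76-fold (-0.82, SE 0.06) and ITGA2, a collagen-binding integrin subunit, fell 1.70-fold (-0.77, SE 0.06). TGFBR2, the type II receptor for transforming growth factor beta, fell 1.57-fold (-0.65, SE 0.06, adjusted p = 0.0243).

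Among the other large falls, the RNA helicase gene DDX1 fell 1.80-fold, the endoplasmic reticulum calcium-binding protein gene CALU 1.72-fold and the carboxypeptidase gene CPA4 1.72-fold. The transmembrane chemokine gene CXCL16 fell 1.68-fold, KRT13, a keratin of stratified epithelium, 1.55-fold, the calcium-binding protein gene S100A14 1.52-fold and ASS1, the argininosuccinate synthase of the urea cycle, 1.51-fold. Adjusted p-values from limma for these 7 genes lay between 0.0166 and 0.0441.

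The 7 rises ranged from 1.36- to 1.61-fold, within the range of the 31 falls (1.30- to 2.45-fold), and 3 of them were in protein-coding genes. DICER1, the endonuclease that produces mature microRNAs, rose 1.43-fold from 6.23 ± 0.05 to 6.74 ± 0.09 (SD, n = 3 each; log2 change 0.51, SE 0.06, limma adjusted p = 0.0421). SOX4, a developmental transcription factor, rose 1.47-fold (adjusted p = 0.0478) and CES1, a liver carboxylesterase, 1.36-fold (adjusted p = 0.043). Among small RNA genes, SNORA72 rose 1.61-fold and SNORA55 1.47-fold. The 2 clusters of SNORA72 disagreed: the median of both gave a log2 change of 0.23. Small nucleolar RNAs have near-identical copies, so these 2 are uncertain.

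The number of calls moved with single arrays. The number of genes past the threshold was 2 without vector replicate 1, 1 without vector replicate 2, 35 without vector replicate 3 (23 of them among the 38), 0 without knockdown replicate 1, 5 without knockdown replicate 2 and 1 without knockdown replicate 3. At an unadjusted limma p under 0.05, 1648 named genes were lower and 1089 higher, with 1123 expected by chance in all. Over all 67528 clusters the balance was the other way, with 2718 lower and 3466 higher and 3376 expected by chance in all. Control and other features had 283 of 2995 at that level, a share no smaller than that of the clusters. Of the clusters, 8 passed: the SND1 cluster, MMP1, CDH1, LGALS4 and 4 clusters with no symbol in the table used, of which TC06000451.hg.1 was higher by 1.40 and TC11003311.hg.1 had a change of -1.30 (log2). Leaving out vector replicate 3 left 4 clusters and leaving out any other array left 0. MMP1 passed in 14 of 16 alternatives, CDH1 in 11 and LGALS4 in 10.

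**Figure D2:**
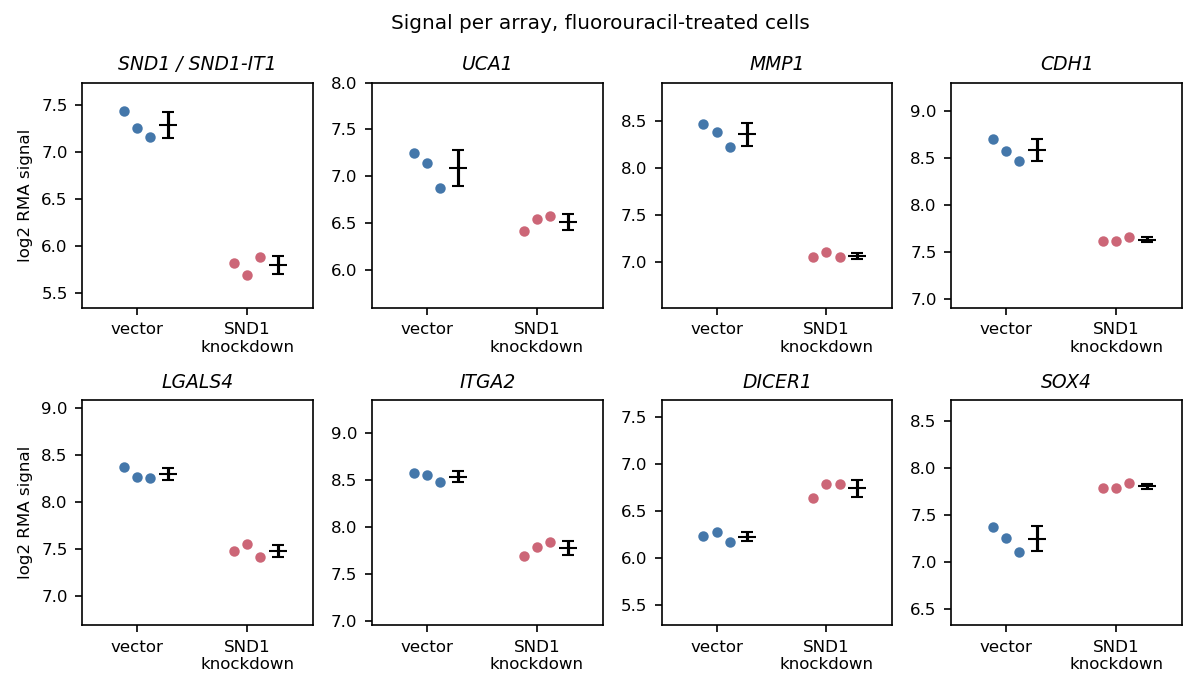
Log2 RMA signal (vertical axis, the same span of 2.4 in every panel) of the SND1 cluster and 7 genes on each array, with blue points for vector and red points for SND1 knockdown. Black marks give the mean and SD of 3 arrays. In each panel all 3 arrays of one group lie beyond all 3 of the other, with the SND1 cluster falling from 7.28 to 5.80 and SOX4 rising from 7.25 to 7.81.

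UCA1, a long noncoding RNA studied in drug resistance and the transcript the study followed up, had a log2 signal of 7.09 ± 0.19 in vector cells and 6.51 ± 0.08 in knockdown cells (SD, n = 3 each). Its change of -0.57 (SE 0.10, 1.49-fold) had a limma adjusted p of 0.0831, and it was lower on 3 of 3 knockdown arrays. Adjusted over the list alone, its p among 27 long noncoding RNAs was 0.012. The study chose UCA1 on these samples, so this is not independent evidence. UCA1 passed in 4 of 15 alternatives, among them that without the dimmest features (adjusted p = 0.0218) and that without vector replicate 3 (0.0468), with adjusted p-values from 0.00354 to 0.316 over the alternatives. No other of the 27 passed over all genes or over the list alone (2 higher and 1 lower at an unadjusted limma p under 0.05, UCA1 included), and MALAT1 and TUG1 had changes of 0.02 (SE 0.08) and -0.06 (SE 0.08). MYB, a transcription factor also linked to the study's question, had signals of 2.27 and 2.26 near the floor of the arrays.

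None of 31 measured genes of fluoropyrimidine metabolism passed over all genes, while 2 were higher and 3 lower at an unadjusted limma p under 0.05. TYMS, the drug's target enzyme, had 7.43 ± 0.06 in vector and 7.47 ± 0.09 in knockdown cells (SD, n = 3 each; change 0.04, SE 0.07), and the pyrimidine kinase gene CMPK1 had a change of 0.13 (SE 0.06). Adjusted over the list alone, RRM2, a ribonucleotide reductase subunit, was higher (0.40, SE 0.06) and the cytidine deaminase gene CDA was lower (-0.33, SE 0.07). These 2 genes, and the others named below as adjusted over the list alone, were picked after their values were seen, except CCN1, CD68, DHCR7 and GDF15, which the rule for named genes gives. None of 14 drug efflux transporters passed over all genes or over the list alone (1 higher and 3 lower at an unadjusted limma p under 0.05), and ABCB1 and ABCC3 had changes of 0.20 (SE 0.07) and -0.18 (SE 0.06). Fry's mixed test, for change in either direction, gave adjusted p = 0.00563 for the fluoropyrimidine list and 0.0308 for the efflux list. It does not compare a list with other genes and called 13 of the 25 lists. Of all 22465 named genes, 2737 had an unadjusted limma p under 0.05, so these values do not set either list apart.

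None of 43 measured p53 targets, 36 pro-apoptotic and 25 anti-apoptotic genes passed over all genes. Of the p53 targets, 3 were higher and 8 lower at an unadjusted limma p under 0.05. MDM2, the ubiquitin ligase that restrains p53, had a signal of 9.92 in both groups (change 0.00, SE 0.06). GDF15, a stress-induced cytokine, had a change of -0.45 (SE 0.08, limma adjusted p = 0.091), the 1 member lower when adjusted over the list alone. The pro-apoptotic genes BNIP3L and DFFA had changes of -0.08 and -0.01, and the anti-apoptotic HSPA5 and TMBIM6 had -0.17 and -0.04. Adjusted over the list alone, 0 genes of either apoptosis list passed, and camera's adjusted p was 0.336 for the pro-apoptotic and 0.146 for the anti-apoptotic list. Fry's mixed adjusted p was 0.00654 for the p53 targets, 0.0186 for the anti-apoptotic and 0.126 for the pro-apoptotic list. Since that test does not compare a list with other genes, these values do not set the lists apart from them. Of the unadjusted limma p-values under 0.05, the pro-apoptotic list had 2, both lower, and the anti-apoptotic list 8, of which 7 were lower.

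Of the 25 lists, camera with its preset correlation called 6 lower and 2 higher in the knockdown, all with mean shifts below 0.12 on the log2 scale. None of the 8 held with an estimated correlation (adjusted p = 0.60 to 0.765) or with fry's directional test (0.0505 to 0.373). Fry's mixed test called 13 of the 25 lists. The array means of the knockdown and vector groups overlapped for 4 of the 8 lists, those of endoplasmic reticulum chaperones, fatty acid and triglyceride genes, mitotic genes and replication genes. Other splits of the 6 arrays into 3 and 3 gave up to 14 called lists. Centring the arrays on their medians moves every gene's change by the same amount, so lists keep their place against other genes. The median change of all genes moved from 0.01 to -0.05, without a change of sign among the means of the 8 lists. The median change was 0.11 for 239 small nucleolar RNA genes and 0.26 for 23 small nuclear RNA genes, but 0.03 for 1040 microRNA genes, against 0.00 for 17082 protein-coding genes.

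The epithelial and cholangiocyte list was shifted lower by a mean of 0.11 (camera adjusted p = 0.000271, adjusted p = 0.60 with an estimated correlation). Of its 26 measured members, 1 (CDH1) fell over all genes and 25 did not pass. Adjusted over the list alone 9 fell, among them the claudin gene CLDN7 (-0.32), the simple-epithelium keratin gene KRT19 (-0.33) and the integrin gene ITGB4 (-0.34). At an unadjusted limma p under 0.05, 9 members were lower and 1 higher. The higher one, named after its value was seen, was CFTR, the chloride channel gene, with a low signal and a change of 0.41 (SE 0.15), which did not pass over all genes or over the list alone. The mean shift was -0.19 without the dimmest 40% of features. That filter drops dimmer members and leaves the change of each other gene as it was. CDH1 (-0.95) weighs more in the smaller set, so this is not a stronger shift of the same genes. The mesenchymal and matrix list had a mean shift of 0.00 and was not called. COL6A1 had a change of 0.05 (SE 0.06), and the matricellular gene CCN1 (-0.35, SE 0.07) was lower when adjusted over the list alone. None of the 34 passed over all genes, with 2 lower at an unadjusted limma p under 0.05.

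Interferon-stimulated genes had a mean shift of -0.08 (camera adjusted p = 0.000271, adjusted p = 0.60 with an estimated correlation). None of 46 members passed over all genes or over the list alone, 12 were lower at an unadjusted limma p under 0.05, 34 had a negative change, and IFI6 and IFITM3 had changes of -0.30 (SE 0.11) and -0.24 (SE 0.08). Targets of ATF4, the transcription factor of the integrated stress response, had a mean shift of -0.09 (camera adjusted p = 0.000317, adjusted p = 0.765 with an estimated correlation). None of 38 passed over all genes (1 higher and 7 lower at an unadjusted limma p under 0.05). NARS1 had a change of -0.13, and GDF15, the amino acid transporter gene SLC7A5 (-0.42) and DDIT3 (-0.32), encoding CHOP, were lower when adjusted over the list alone. Endoplasmic reticulum chaperones and unfolded protein response genes had a mean shift of -0.09 (camera adjusted p = 0.00157, adjusted p = 0.765 with an estimated correlation). None of 31 passed over all genes (9 lower at an unadjusted limma p under 0.05), CALR and HSPA5 had changes of -0.06 and -0.17, and 4 genes including ATF6 (-0.28) and HERPUD1 (-0.31) were lower over the list alone. Without vector replicate 1 the mean shifts of these 2 stress lists were -0.05 each. With arrays centred they were -0.14 each, as was that of the interferon list, through the same move of all genes. Without the dimmest features, which drops dimmer members, the interferon shift was also -0.14.

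Sterol synthesis genes had a mean shift of -0.08 (camera adjusted p = 0.00301, adjusted p = 0.765 with an estimated correlation). None of 23 passed over all genes (3 lower at an unadjusted limma p under 0.05), while the sterol synthesis enzyme genes CYP51A1 (-0.41, SE 0.06) and DHCR7 (-0.38, SE 0.07) were lower over the list alone, and TM7SF2 had -0.07. Fatty acid and triglyceride genes had a mean shift of -0.06 (camera adjusted p = 0.00519, adjusted p = 0.765 with an estimated correlation), and none of 28 passed over all genes (1 higher and 7 lower at an unadjusted limma p under 0.05). Over the list alone, DGAT1 (-0.29) and MLXIPL (-0.21) were lower and PLIN2, a lipid droplet coat protein, was higher (0.27), while ME1 and PLIN3 had -0.09 and -0.12. This call ended without vector replicate 1 (mean shift -0.04, camera adjusted p = 0.0531). With arrays centred, the sterol and fatty acid shifts were -0.14 and -0.12, again through the move shared by all genes.

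Mitotic and replication genes were the 2 lists called higher. The 45 mitotic genes had a mean shift of 0.10 (camera adjusted p = 1.59e-05, adjusted p = 0.765 with an estimated correlation), 41 with a positive change. The proliferation marker MKI67 had a change of 0.23 (SE 0.06) and the spindle factor TPX2 0.03 (SE 0.07), and none of the 45 passed over all genes or over the list alone, with 10 higher at an unadjusted limma p under 0.05. The 44 replication genes had a mean shift of 0.08 (camera adjusted p = 0.000271, adjusted p = 0.765 with an estimated correlation), 36 positive, and none passed either way, with 8 higher at an unadjusted limma p under 0.05. Their members PCNA and POLD2 had changes of -0.16 (SE 0.07) and 0.01 (SE 0.05). With arrays centred the 2 mean shifts were 0.04 and 0.02, as the change of every gene moved down alike. Both calls stayed (camera adjusted p = 0.000294 and 0.00288). The replication call ended without vector replicate 3 (mean shift 0.05, camera adjusted p = 0.0636).

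Camera with its preset correlation did not call the other 17 lists (adjusted p = 0.122 to 0.99). The mean and the median change differed in sign for 3 lists, those of hepatocyte plasma proteins (-0.01 and 0.01), hepatocyte metabolism (-0.01 and 0.00) and long noncoding RNAs (-0.01 and 0.02), and camera's direction for the first was up. FABP1, the liver fatty acid-binding protein gene, fell 1.37-fold at a low level (4.40 to 3.94, limma adjusted p = 0.0414) and was the 1 of 27 fatty acid oxidation genes to pass. ASS1 was the 1 of 45 hepatocyte metabolic genes, CXCL16 the 1 of 33 NF-kappaB and inflammatory genes and DICER1 the 1 of 29 SND1 partner and RNA-silencing genes to pass. At an unadjusted limma p under 0.05, the fatty acid oxidation list had 0 members higher and 2 lower, the hepatocyte metabolic list 2 and 4, the NF-kappaB list 1 and 6 and the SND1 partner list 1 and 3. Over the list alone, JUNB (-0.34, SE 0.06), a transcription factor gene of the NF-kappaB list, was also lower. Of 45 plasma protein genes none passed over all genes, APOA2 and APOE had changes of 0.08 and -0.15, and SERPINA1 (-0.43) was lower over the list alone (2 higher and 3 lower at an unadjusted limma p under 0.05). No member passed over all genes among 48 DNA repair genes (XRCC5 0.07, APEX1 0.00), 17 replication histone genes (H2BC12 0.00, H2AC20 0.05), 34 glycolysis and hypoxia genes (SLC2A1 -0.29, PKM -0.11) and 36 ribosome biogenesis genes (NOP10 -0.13, NCL 0.00). At an unadjusted limma p under 0.05 these 4 lists had 5, 1, 0 and 1 members higher and 0, 1, 3 and 0 lower, and none passed over the list alone. None of 25 leukocyte and endothelial markers passed over all genes. CD68, a lysosomal protein gene used as a macrophage marker, had a change of -0.55 (SE 0.09) and CLDN5 one of 0.17 (SE 0.11). At an unadjusted limma p under 0.05 only CD68 of the 25 was lower and 0 were higher, and CD68 was lower over the list alone.

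**Figure D3:**
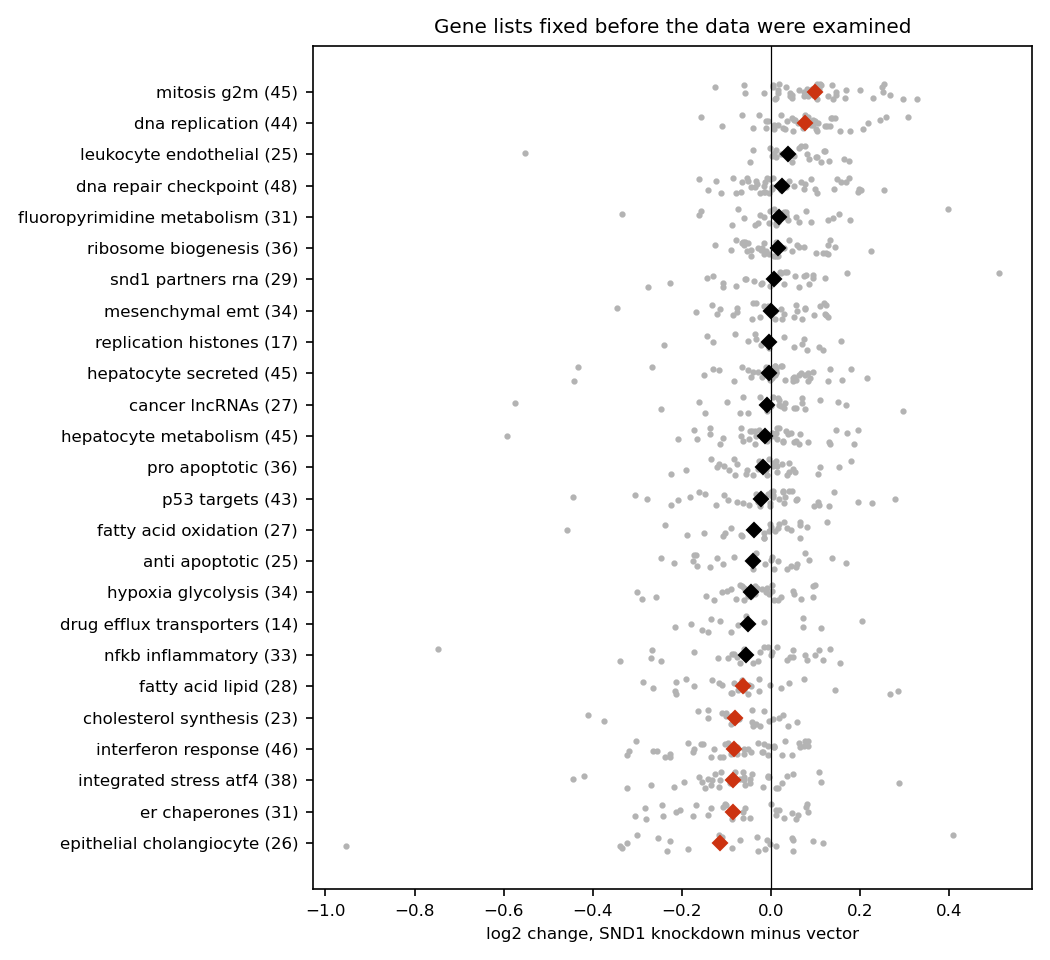
Log2 change of each measured member (grey points; horizontal axis, knockdown minus vector) of the 25 gene lists, with the number of members in parentheses and the list mean as a diamond. Red diamonds mark the 8 lists called by camera with its preset correlation, whose means run from -0.11 (epithelial) to 0.10 (mitotic), and none of which was called with an estimated correlation.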

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

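All 38 genes had an unadjusted limma p under 0.05 in every alternative that tested them. Their kept direction says little, since their groups do not overlap and several alternatives leave the change as it is. The number of genes changed (higher, lower) was 38 (7, 31) as reported. It became 1 (0, 1) with the replicate block, 271 (84, 187) without the dimmest 40% of features, 61 (12, 49) after renewed quantile normalization, 15 (1, 14) with arrays centred on their medians, 0 (0, 0) with the floor on low values, 133 (27, 106) with the variance trend and robust fitting, 3212 (1559, 1653) with array weights, 1 (0, 1) with a 2-fold minimum and 123 (10, 113) among protein-coding genes only, an alternative chosen after seeing the data. The share of calls that were higher was 18.4% as reported, 31% without dim features, 6.7% after centring, 48.5% with array weights and 8.1% among protein-coding genes. Without dim features, many of the higher calls were copies of ribosomal or small nuclear RNA genes. Array weights ranged from 0.449 to 7.77 and their estimation stopped before it converged. Leaving out single arrays gave 0 to 35 genes (0 to 6 higher, 0 to 29 lower) and 0 to 4 clusters. The 8 clusters changed became 0 with the replicate block, 1 with the floor, 24 with the variance trend and 29 with array weights. At the floor's 0 genes, all 38 had an unadjusted p under 0.05. The dim filter and the protein-coding alternative test fewer genes, and single omissions fit fewer arrays. With the floor, SND1 and UCA1 lay above it and kept changes of -1.49 and -0.57, while limma's adjusted p rose to 0.178 and 0.227. Their rise thus came from how other genes entered limma's variances or the adjustment, not from their own signals. Why the remaining alternatives moved the counts was not tested. The SND1 change was -1.49 with the replicate block (adjusted p = 0.142) and with the floor (0.178), and -1.41 to -1.55 without single arrays. The replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.364, 0.107 and -0.486, and not every array correlated best with its own number. Among lists, 8 were called as reported, 7 to 10 without single arrays, 0 with an estimated correlation and 0 with fry's directional test, while its mixed test called 13; the other alternatives called 8 or 9. Of the called lists' results over the other alternatives, the replication list lost its call without vector replicate 3 and the fatty acid list without vector replicate 1. For single genes, 128 results fell short of the threshold in an alternative, 22 passed it only there and 0 reversed. For lists these numbers were 18, 6 and 0, and signs of genes and lists past the threshold in neither setting were not compared. Dim genes, such as MYB, lie where the signal is compressed.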

Other observations

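The tests of the intestinal-type markers, of the small RNA gradient and of other splits of the arrays were specified before their results were seen. The tests of hepatocyte and epithelial levels, of untreated arrays, of shifted gene names and of the neighbours of SND1 were chosen only after the result was seen.

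Without the dimmest 40% of features, 187 genes fell and 84 rose, and 36 of the 38 genes of the report were tested and remained. The following genes were picked after their values were seen, with limma adjusted p-values from that alternative. None of them passed in the main fit over all genes (limma adjusted p = 0.0531 to 0.138). Among those that fell were the laminin-binding integrin subunit genes ITGA3 (-0.48, adjusted p = 0.0141) and ITGA6 (-0.30, 0.031), the receptor tyrosine kinase genes AXL (-0.48, 0.0155) and ERBB3 (-0.35, 0.0499), the transcriptional coactivator gene YAP1 (-0.39, 0.0178) and the kinase gene JAK1 (-0.48, 0.0113). MUC2, the secreted gel-forming mucin of the gut, fell by 0.39 (0.0178). LGR5, a stem cell receptor gene, rose by 0.48 (0.044), RRM2 by 0.40 (0.0218) and IGF2BP3, encoding an oncofetal RNA-binding protein, by 0.35 (0.0255). Of the 84 genes that rose, 30 were pseudogenes and 20 small nucleolar RNA genes, against 16 protein-coding genes. All 30 pseudogenes were copies of ribosomal or small nuclear RNA genes. A further 11 genes with no class given were also small nuclear RNA copies. Some copies had identical changes, such as 0.33 (SE 0.07) for RNU6-1, RNU6-11 and RNU6-37, so these rises are not all separate results.

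On arrays labelled HepG2, ALB and AFP lay below the 10th percentile of named genes, and the median level percentile was 38.9 for the plasma protein list and 81.7 for the epithelial list, but probes differ in how strongly they report a transcript, and 0 arrays labelled with another cell line were analysed here to set the same probes against. A cell type other than the label's, which might give such signals, and low signal of these probes in general therefore both stay open. A shift of all gene names against the values is argued against by the SND1 cluster, which fell as targeted and had rank 2 by p among 67528 clusters, though this covers no errors in single names. Open too is an effect of fluorouracil on liver genes, as 0 arrays of untreated cells were analysed here. Of the intestinal-type genes, CDH17, MUC13 and KRT20 lay above the 98th percentile and SI and FABP2 near the floor. The 22 members whose levels had not been looked at had a median at the 59.4th percentile of 10000 random lists of protein-coding genes. The members left out had levels seen before, the lowest at the 72.7th percentile, so leaving them out lowered that median. Above the 75th percentile lay 6 of the 22 and 12 of all 29, and 5 of the 22 lay below the 25th. As probes differ in how strongly they report a transcript, these values do not settle an intestinal type.

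The small nuclear RNA, small nucleolar RNA and pseudogene classes had higher medians in the knockdown. The mean of the epithelial list was lower, a call lost with an estimated correlation (camera adjusted p = 0.60) and with fry's directional test (0.0505). Median changes were 0.26 for 23 small nuclear RNA genes, 0.11 for 239 small nucleolar RNA genes and 0.14 for 936 pseudogenes, and each of these 3 class medians had the smallest exact permutation p the design allows, 0.1. They were 0.03 for 1040 microRNA genes (exact permutation p = 1), 0.03 for 1840 long noncoding RNA genes (0.3) and 0.00 for 17082 protein-coding genes (0.8). A gradient between arrays in the yield or labelling of small nuclear and nucleolar RNA could move other genes with it. Within groups, the slope of the mitotic list on the median of the 262 small nuclear and nucleolar RNA genes predicted a change of -0.18 (95% interval -0.36 to 0.01). The observed 0.10 lay outside, which argues against a linear effect of this gradient on the mitotic list. That median was 4.77 to 4.83 on vector and 4.94 to 5.10 on knockdown arrays, so the slope was extended beyond the spread within groups. Other array-wide differences are not covered. Centring the arrays on their medians gave a mitotic shift of 0.04 but moved all genes alike, so it does not test the gradient. For the epithelial list the slope predicted -0.03 (interval -0.11 to 0.05) against the observed -0.11, at the edge of the interval. The 6 arrays thus leave the gradient and an effect of the knockdown open for that list.

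CALU and CPA4 lie near SND1 on chromosome 7 and fell 1.72-fold each, which might reflect a loss of the region in the knockdown cells. The other 31 genes above the median level within 5 Mb had a median log2 change of -0.02 (95% bootstrap interval -0.09 to 0.02). Of them 0 passed, a threshold that few genes passed at all. The median argues against a loss of most of this window. A smaller loss that spares most of these genes would not move it and stays open. An off-target effect of the hairpin was not tested, as its sequence was not used here.

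The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 38 genes and 8 clusters, each reached by 1 of the 10 splits, and the highest other split gave 0 genes and 0 clusters. For gene lists, 4 of the 10 splits gave at least the real 8 lists, and the highest other gave 14.

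Of the 2995 control and other features, limma called 0 (lowest adjusted p = 0.0679). At an unadjusted limma p under 0.05 there were 283, more than the share of 0.05 that chance gives. Of the 67528 transcript clusters 6184 lay at that level, a share no larger than that of the control and other features. The excess among the clusters therefore does not by itself show an effect of the knockdown. The 92 spike-in control features had a median log2 signal of 3.08 on vector and 3.22 on knockdown arrays. As controls they report no transcript of the cells, yet this gap was larger than the reported mean shift of any called list. Whether it bears on the lists was not tested.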
